A study of Candida albicans with 5 samples.

How the data were processed

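Strand-specific paired-end RNA sequencing with 100 bp reads was done on Candida albicans, from 100 ng of RNA per library per the labels' protocols. The values are estimated counts (expected counts) per gene that the authors deposited in a single table for all 5 libraries. Per the submitters' processing notes, cutadapt (version not given), STAR 2.7.10b and RSEM 1.3.3 were used. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. RSEM divides reads that fit several genes between them, and between 2.66% and 2.95% of the values in a library were not whole, so genes with near-identical copies are uncertain. The protocol names both a kit that selects messenger RNA and removal of ribosomal RNA, and the ribosomal RNA genes held between 0.69% and 1.24% of the counts.

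Groups were taken from the sample titles, which give 2 untreated controls and 3 samples treated with compound 2. Other label fields are at odds with the titles: the library names of the treated samples begin with letters that could be read as untreated, and their treatment field names tavaborole as well as compound 2. The direction of every difference therefore rests on the titles. The protocol gives a microdilution range of 0.5 to 64 µg/mL but not the dose or the time used for RNA. Whether the controls received solvent is not stated, and all libraries carry the same batch label. Table columns were assigned by the library number that ends each sample's description, and 0 columns were left unassigned. No pair of replicates agreed within sampling noise in a chi-square test of their counts (98.3 to 171 per degree of freedom).

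The table held 6468 genes, of which 308 were at 0 in every library. Gene names came from a reference table for assembly ASM18296v3, which was used for names only, so no coordinates are given. Of the identifiers, 6263 matched it by locus tag, 205 did not and 2962 had a symbol. BOR1, a boron efflux gene chosen in advance, was matched to no symbol and is not reported.

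Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, libraries scaled with TMM factors (0.89 to 1.12) and groups compared with edgeR 4.0.16 (quasi-likelihood test) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression values are TMM-scaled CPM, and folds are fitted values. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 36 lists. Lists added later were adjusted apart, over the added lists alone. They were also tested with a correlation estimated per list and with limma's fry. Figures were drawn with matplotlib 3.10.9.

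The design, the 36 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap. It added CDC60, NAM2 and BOR1, and up to 4 called members of each list with the largest change, or the 2 with the smallest p where none was called. Other genes were named without a fixed rule, most of them after their values were seen. A few genes that the rule or a small count would name are not reported here.

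The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals alone, no filter on low counts, a filter of at least 50 counts in at least 2 libraries, robust dispersion, the replicate number as a block, and leaving out each library. For lists they also included camera on ranks. A run without the 4 ribosomal RNA genes was added after the data were seen.

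The method was tested on simulated data for this comparison with 5883 genes, drawn from the means and totals of these libraries. With 100 genes changed by 2-fold and 100 by 4-fold, edgeR recovered 54% and 95%, and 9 of 158 calls were false (5.7%). A planted list of 20 genes changed by 2-fold was called by camera (adjusted p = 2.24e-16) and fry (adjusted p = 0.017). It was missed with an estimated correlation (adjusted p = 0.0931), and 0 of 36 random lists were called by any of these tests. Simulated genes varied independently of each other, so the simulation cannot show how these tests treat lists whose members vary together. For the same reason, its share of false calls need not hold for real libraries in which many genes deviate together. At totals of 20345574 to 28199926 counts, the spread between replicates (biological coefficient of variation 24.4%), not counting error, limits most genes.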

Results

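RNA was sequenced from 5 samples of wild-type Candida albicans, a yeast that lives in people and can cause disease. The control group held 2 untreated samples and the other group held 3 samples treated with compound 2, a bis(benzoxaborole) related to tavaborole. Tavaborole is a boron-containing antifungal drug that blocks leucyl-tRNA synthetase, the enzyme that loads leucine onto its transfer RNA. The deposited table gave estimated counts per gene, and their totals were 28199926 and 23164193 in control replicates 1 and 2. The totals were 22989656, 21775811 and 20345574 in compound 2 replicates 1, 2 and 3. Between 5993 and 6086 genes had at least 1 count in a library. The first principal component held 50.4% of the variance, with the controls at -36.8 and -20.4 and the treated libraries at 10.5, 25.9 and 20.7. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels used here do not state the dose or the exposure time of the sequenced samples.

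The comparison of treated with untreated samples asked which transcripts differ in cells exposed to compound 2, as part of a study of how this compound acts. MDR1 (C6_03170C_A), which encodes a multidrug efflux pump, rose 31.6-fold, from 5.34 ± 1.10 CPM (counts scaled to a common library size; SD, n = 2) to 169.5 ± 5.33 CPM (SD, n = 3). IFD6 (C1_04140W_A), of the aldo-keto reductase family, rose 9.86-fold, and LEU4 (C1_00170W_A), which encodes the enzyme that opens leucine synthesis, rose 6.55-fold. The log2 fold change of LEU4 was 2.71, and 3.47 without control replicate 2. INO1 (CR_10100C_A), which encodes inositol-1-phosphate synthase, fell 20.8-fold, from 251.4 ± 63.3 to 12.1 ± 5.68 CPM. CYB2 (C1_13630W_A), a lactate dehydrogenase gene, fell 5.81-fold, and OSM2 (C1_13670W_A), a fumarate reductase gene, fell 5.82-fold.

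edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 504 of 5908 genes at an adjusted p under 0.05, with 297 higher and 207 lower in the compound 2 libraries. Of these, 218 were higher and 139 lower by at least 2-fold. All 3 treated libraries lay above both controls for 294 of the 297 higher genes, and below both for all 207 lower genes. Over all tested genes, 40.5% had groups that did not overlap, where chance gives 20%. The log2 fold changes and adjusted p-values from edgeR were 4.98 ± 0.30 (SE, as for every log2 fold change given with an error) and 6.89e-09 for MDR1, 3.30 ± 0.32 and 5.88e-06 for IFD6, and 2.71 ± 0.36 and 0.00011 for LEU4. They were -4.38 ± 0.32 and 1.43e-07 for INO1, -2.54 ± 0.25 and 5.88e-06 for CYB2, and -2.54 ± 0.27 and 1.8e-05 for OSM2. With library totals as the only scaling, the median of all genes moved by -0.20 on the log2 scale and the split became 184 higher and 414 lower (30.8% higher, against 58.9% with TMM factors). The counts also depended on single libraries, with 172 higher and 97 lower without control replicate 1, and 340 and 331 without control replicate 2. They were 452 and 425 without compound 2 replicate 1, 162 and 82 without replicate 2, and 141 and 78 without replicate 3.

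Other genes that rose at the top of the ranking were ILV5, the ketol-acid reductoisomerase gene of isoleucine and valine synthesis (4.89-fold), OYE32, an NADPH oxidoreductase gene (4.65-fold), and MET15, an O-acetylhomoserine sulfhydrylase gene (4.59-fold). ALK8, a cytochrome P450 gene, rose 4.86-fold, FAD3, a fatty acid desaturase gene, 4.67-fold, and TNA1, a putative nicotinic acid transporter gene, 4.61-fold. HYR1, a hyphal cell wall protein gene, rose 4.52-fold from 6.85 ± 2.54 to 31.1 ± 7.28 CPM, and LYS22, a homocitrate synthase gene of lysine synthesis whose counts were partly non-whole, rose 4.08-fold. PMS1, a DNA mismatch repair gene, rose 4.21-fold (log2 2.08 ± 0.53). Its call was lost without control replicate 1 (1.67) or compound 2 replicate 3 (1.6).

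Among the other genes that fell, SUR2, a sphingolipid hydroxylase gene, was 3.87-fold lower, and AUR1, which encodes inositolphosphorylceramide synthase, was 3.71-fold lower. RBR1 and SSR1, which encode cell wall proteins, were 4.26-fold and 3.44-fold lower. Without control replicate 1, the log2 fold changes of SUR2 and SSR1 went from -1.95 and -1.78 to -1.09 for both, and both kept their calls. PUT1, a proline dehydrogenase gene, was 3.41-fold lower, and AXL1, an endoprotease gene, was 3.58-fold lower. GCA2, a glucoamylase gene with partly non-whole counts, was 3.56-fold lower. RDN58, a short ribosomal RNA gene, was 3.91-fold lower, from 103.2 ± 29.0 to 26.4 ± 3.92 CPM. AAT22, an aspartate aminotransferase gene, was 3.47-fold lower, with a log2 fold change of -1.79 ± 0.40. That call was lost without control replicate 1 (-1.18) or compound 2 replicate 3 (-1.81).

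**Figure D1:**
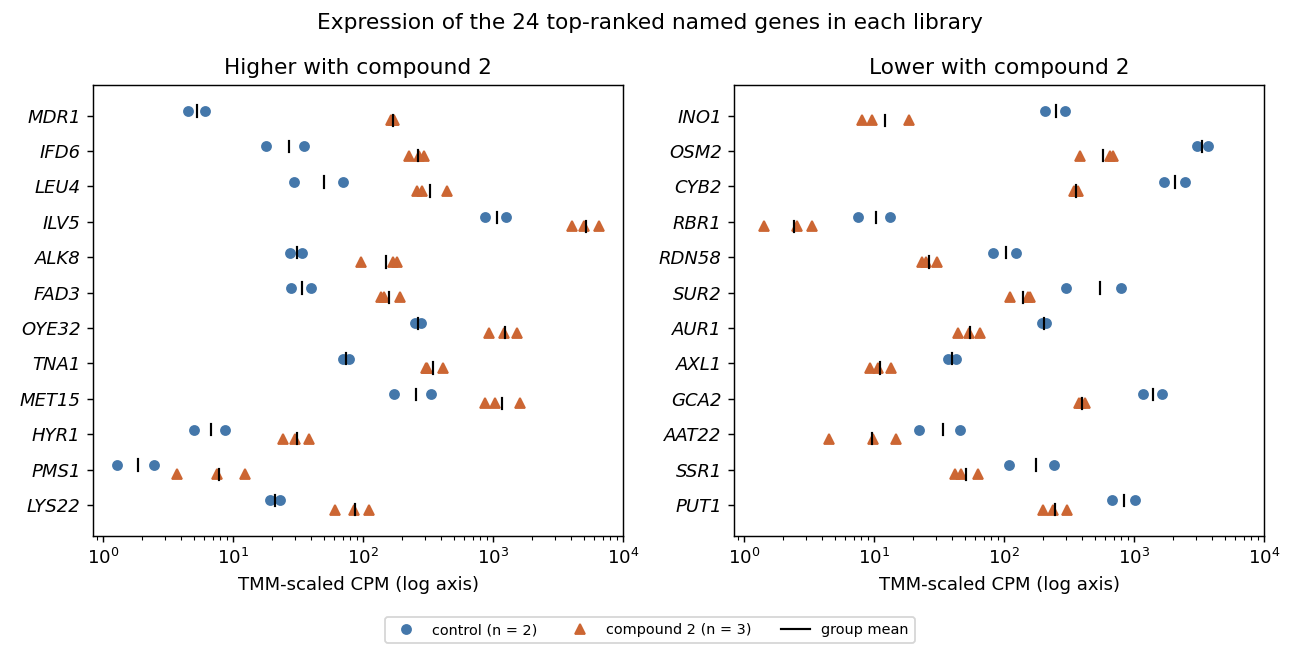
Expression of the 12 top-ranked higher genes (left) and the 12 top-ranked lower genes (right) in each of the 5 libraries, in TMM-scaled CPM on a log axis, with circles for control, triangles for compound 2 and bars for group means. MDR1 lay at 4.56 and 6.12 CPM in the controls and between 163.7 and 174.1 CPM in the treated libraries, and INO1 at 206.7 and 296.2 CPM in the controls and between 8.04 and 18.6 CPM in the treated libraries.

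CDC60 (CR_01690C_A), which encodes the cytosolic leucyl-tRNA synthetase that tavaborole blocks, was at 484.0 ± 34.2 CPM (SD, n = 2) in the controls and 539.6 ± 64.7 CPM (SD, n = 3) with compound 2. Its log2 fold change was 0.16 ± 0.24 (SE) with an adjusted p of 0.735 in edgeR's test, so no difference larger than the spread between replicates was found. NAM2, the gene of the mitochondrial leucyl-tRNA synthetase, had a log2 fold change of 0.06 ± 0.26 and an adjusted p of 0.924. None of the 18 cytosolic aminoacyl-tRNA synthetase genes was called (0 adjusted over the list alone). Their median log2 fold change was 0.24 and the list test (limma's camera) gave an adjusted p of 0.244. A single member was lower without control replicate 2 and with library totals as the only scaling (1 of 18 in each). The members with the smallest p-values were ALA1 at -0.63 ± 0.25 (adjusted p 0.126) and DED81 at 0.57 ± 0.24 (adjusted p 0.157).

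Most of the listed genes of leucine, isoleucine and valine synthesis rose. Of 11 tested members, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median log2 fold change of 1.33. Besides LEU4 and ILV5, they included the acetolactate synthase genes ILV2 (1.67 ± 0.25) and ILV6 (1.58 ± 0.25). LEU2 (1.45 ± 0.26), LEU1 (1.33 ± 0.25) and ILV3 (0.88 ± 0.27), named after their values were seen, were the rest. The call of ILV3 was lost without control replicate 1 (0.60) or compound 2 replicate 2 (0.72) or 3 (0.96). LEU42, ILV1, BAT21 and BAT22, also named after their values were seen, were not called, with log2 fold changes between -0.14 for ILV1 and 0.66 for BAT22. The list was higher by camera (adjusted p = 6.16e-07), with adjusted p = 0.455 with an estimated correlation.

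Of 19 tested genes of sulfur assimilation and methionine synthesis, 9 were higher and 0 lower (12 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.69. Examples were MET15 (2.20 ± 0.33), the ATP sulfurylase gene MET3 (1.94 ± 0.29), the sulfate transporter gene SUL2 (1.90 ± 0.27) and the cystathionine gamma-lyase gene CYS3 (1.57 ± 0.26). Camera gave adjusted p = 6.16e-07, and adjusted p = 0.499 with an estimated correlation. In the list of other amino acid synthesis genes, 11 of 43 were higher and 3 lower (17 and 4 adjusted over the list alone). LYS22 (2.03 ± 0.28), HOM6 (1.61 ± 0.25) of threonine and methionine synthesis, HIS5 (1.56 ± 0.24) of histidine synthesis and LYS12 (1.43 ± 0.24) of lysine synthesis rose. The lower members included ARG1 (-1.37 ± 0.26) and ARG4 (-1.20 ± 0.35) of arginine synthesis, named after their values were seen. The list was higher by camera (adjusted p = 6.58e-05), with adjusted p = 0.246 with an estimated correlation. Without control replicate 1 or compound 2 replicate 2, 5 sulfur genes were higher, and 4 and 5 of the other amino acid genes. Without compound 2 replicate 3 the latter were 6. Scaling by library totals gave 6 sulfur genes higher and 1 lower, and 7 and 4 of the other list, and without control replicate 2, 1 sulfur gene was lower. Without control replicate 1 or compound 2 replicate 2 or 3, the lower members were 1 in each case, and ARG4 lost its call (-0.53, -1.34 and -1.03).

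In the multidrug efflux list, MDR1 was among 9 higher genes of 28, with 0 lower and 19 not called (11 higher and 1 lower adjusted over the list alone), and the median log2 fold change was 0.29. YOR1, an ABC transporter gene, rose 2.69-fold (log2 1.43 ± 0.30). RTA4, of a lipid-translocating exporter family, rose from 0.968 CPM (log2 2.35 ± 0.59), and PDR16, a phosphatidylinositol transfer protein gene, rose 2.53-fold (log2 1.34 ± 0.35). The ABC pump genes CDR1 and CDR2, which the rule for named genes did not take, were not called, with log2 fold changes of 0.03 ± 0.27 (adjusted p 0.967) and 0.25 ± 0.25 (adjusted p 0.581), from partly non-whole counts. The list was higher by camera (adjusted p = 0.00342), with adjusted p = 0.576 with an estimated correlation. RTA4 was at 3.46 without control replicate 1 and lost its call without control replicate 2 (1.76), as did PDR16 (1.14), which was also lost without compound 2 replicate 2 (1.38). The number of higher members was 5 without control replicate 1, 4 without control replicate 2, 3 without compound 2 replicate 2 and 5 without compound 2 replicate 3. Without compound 2 replicate 1, 8 were higher and 2 lower, and scaling by library totals gave 4 and 1.

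Oxidative stress defence genes were higher for 12 of 33 members and lower for 0 (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.59. OYE32 (2.22 ± 0.28) and OYE23 (1.76 ± 0.34), of the old yellow enzyme family, and the glutathione S-transferase genes GST1 (1.53 ± 0.40) and GST3 (1.34 ± 0.27) rose most. Camera gave adjusted p = 4.46e-06, and adjusted p = 0.324 with an estimated correlation. GST1 was not called without control replicate 2 (1.15) or compound 2 replicate 2 (1.46) or 3 (1.26). In those same fits 7, 7 and 6 members were called, and 7 were when scaled by library totals.

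In 3 lists of central carbon metabolism, some members rose and 0 fell. In glycolysis and fermentation, 12 of 20 were higher and 0 lower (13 and 0 adjusted over the list alone). The pyruvate decarboxylase gene PDC11 (1.31 ± 0.29), the hexokinase gene HXK2 (1.3 ± 0.25), the aldolase gene FBA1 (1.14 ± 0.24) and the phosphofructokinase gene PFK2 (1.09 ± 0.27) led the list. In the tricarboxylic acid cycle, 6 of 19 were higher and 0 lower (8 and 0 adjusted over the list alone), led by the isocitrate dehydrogenase gene IDP1 (1.98 ± 0.29). In the respiratory chain and ATP synthase, 7 of 32 were higher and 0 lower (10 and 0 adjusted over the list alone). AOX2, an alternative oxidase gene, rose 3.36-fold from 750.9 ± 267.2 to 2520 ± 412.3 CPM, and NDE1, an NADH dehydrogenase gene, rose 2.24-fold. The medians were 0.89, 0.60 and 0.48, and camera's adjusted p-values 1.29e-06, 2.38e-05 and 5.61e-06. They became adjusted p = 0.204, adjusted p = 0.571 and adjusted p = 0.204 with an estimated correlation. The called members fell to 5, 1 and 2 without control replicate 1, to 6, 1 and 2 without compound 2 replicate 2 and to 5, 2 and 2 without compound 2 replicate 3. Without control replicate 2 the respiratory chain had 11 called members, and scaling by library totals gave 9, 2 and 2 in the 3 lists.

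Most genes of ribosomes and their assembly were not called. Cytosolic ribosomal protein genes had a median log2 fold change of 0.43, with 2 of 73 higher and 0 lower (1 and 0 adjusted over the list alone). These were RPL3 (1.28 ± 0.26) and RPL2 (0.93 ± 0.26). Ribosome biogenesis genes had a median of -0.37, with 5 of 70 lower and 0 higher (7 and 0 adjusted over the list alone). They were NOP14 (-1.23 ± 0.28), KRR1 (-1.06 ± 0.27), ENP2 (-0.98 ± 0.28), UTP20 (-0.93 ± 0.25) and, named after its values were seen, UTP22 (-0.85 ± 0.26). Camera called the first list higher (adjusted p = 6.16e-07, but adjusted p = 0.549 with an estimated correlation) and the second lower (adjusted p = 6.58e-05, but adjusted p = 0.744 with an estimated correlation). No biogenesis gene was called (0 of 70) without control replicate 1, where NOP14 was at -0.84, or without compound 2 replicate 2 (-1.13) or 3 (-1.05). There were 19 such genes without control replicate 2, 18 without compound 2 replicate 1 and 12 when scaled by library totals, all of them lower. RPL2 lost its call in the same 3 fits (0.69, 0.95 and 0.81), whereas 12 ribosomal protein genes were higher and 3 lower without control replicate 2, and 11 and 0 without compound 2 replicate 1. Scaling by library totals gave 1 higher and 1 lower.

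Proteasome genes had a median log2 fold change of 0.56 over 26 members, of which 1, PRE6 (0.93 ± 0.27), was higher and 0 lower (6 and 0 adjusted over the list alone). Cell cycle genes had a median of 0.61, with 6 of 30 higher and 0 lower (7 and 0 adjusted over the list alone). The cyclin gene PCL2 rose from 0.856 ± 0.184 to 7.25 ± 2.86 CPM (log2 3.08 ± 0.54). The ribonucleotide reductase gene RNR1 (1.63 ± 0.31) and the mitotic kinase gene CDC5 (1.47 ± 0.27) were higher too. RNR1 was at 2.23 without control replicate 2. In the histone list, CSE4 (1.52 ± 0.30), the centromeric histone gene, and HTA1 (1.00 ± 0.27) were the 2 higher of 11, with 0 lower (2 and 0 adjusted over the list alone). In the list for folding and secretion in the endoplasmic reticulum, 3 of 18 were higher and 0 lower (4 and 0 adjusted over the list alone). These were the chaperone gene KAR2 (1.02 ± 0.24), the disulfide isomerase gene PDI1 (0.91 ± 0.24) and the mannosyltransferase gene PMT4 (0.84 ± 0.24). Camera's adjusted p-values for the 4 lists were 1.7e-06, 2.41e-05, 0.0146 and 0.00204, and with an estimated correlation they were adjusted p = 0.591, adjusted p = 0.576, adjusted p = 0.576 and adjusted p = 0.314. The histone list was not called without control replicate 1. Without control replicate 1, PRE6 (0.71), HTA1 (0.75), KAR2 (1.00), PDI1 (0.88) and PMT4 (0.83) lost their calls, as they did without compound 2 replicate 2 (0.86, 1.00, 0.99, 0.88 and 0.92). Without compound 2 replicate 3 all of these but KAR2 did so (0.78, 0.83, 0.92 and 0.93). PDI1 and PMT4 were also lost without control replicate 2 (0.93 and 0.86), and PMT4 without compound 2 replicate 1 (0.70), where 8 proteasome genes were called, against 3 without control replicate 2. Scaling by library totals left 0 proteasome genes, 4 cell cycle genes, 1 histone gene and 1 gene of the endoplasmic reticulum list higher.

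**Figure D2:**
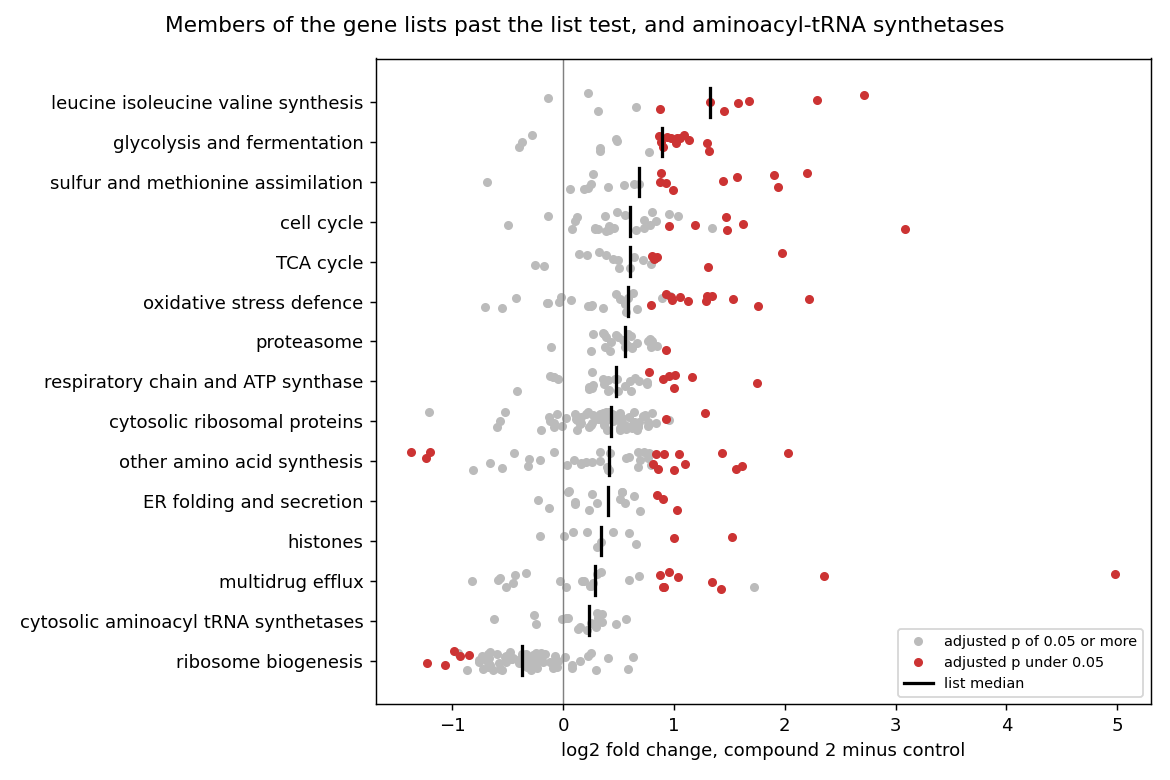
Log2 fold changes (compound 2 minus control, horizontal axis) of the members of the 14 lists past camera's threshold and of the aminoacyl-tRNA synthetase list, with a point per gene, red where edgeR's adjusted p was under 0.05 and a bar at each list median. The branched-chain amino acid list had the highest median (1.33) and ribosome biogenesis the lowest of these 15 (-0.37).

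Genes that mark other cell forms did not move together. Of 27 adhesin and hyphal genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; camera's adjusted p = 0.271). HYR1 (2.18 ± 0.34) and IHD1 (1.76 ± 0.34), a GPI-anchored protein gene, rose, as did ALS1 (1.07 ± 0.27), an adhesin gene with partly non-whole counts, and RBT4 (1.00 ± 0.26). ALS9, named after its values were seen, was at -0.86. Without control replicate 2, IHD1 was at 2.62. The yeast-form wall protein gene YWP1 fell 2.68-fold, from 2780 ± 193.5 to 1036 ± 415.8 CPM, while RHD3 of the same list rose 2.26-fold, so that 1 of 10 was higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.944). In the opaque and mating list, AXL1 was the 1 lower of 13 and 0 were higher (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.568). These counts became 2 higher and 3 lower without control replicate 2, and 0 and 2 when scaled by library totals. In the vitamin and stationary-phase list, SNZ1, a pyridoxine synthesis gene, rose 3.37-fold and was the 1 called of 9 (2 adjusted over the list alone; adjusted p = 0.384), or of 2 called without control replicate 2 or compound 2 replicate 1. ALS1 was not called without control replicate 2 (0.89) or compound 2 replicate 2 (0.85), RBT4 not without control replicate 1 (0.91) or compound 2 replicate 2 (0.94), and ALS9 not without control replicate 1 (-0.59) or compound 2 replicate 2 (-0.86) or 3 (-0.78). RHD3 was not called without control replicate 2 (0.91) or compound 2 replicate 2 (1.04) or 3 (1.02).

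Cell wall and membrane lists were not called either. The glucan remodelling gene CRH11 (1.3 ± 0.27) was among 4 higher of 30 glucan genes, with 0 lower (4 and 0 adjusted over the list alone; camera's adjusted p = 0.902), beside EXG2 (1.47 ± 0.35) and SCW11 (0.86 ± 0.24). In the chitin list CHS1 (1.51 ± 0.31), a chitin synthase gene, and CHT2 (1.01 ± 0.24), a chitinase gene, were higher and CHS4 (-0.83 ± 0.24) lower among 17 (2 and 2 adjusted over the list alone; adjusted p = 0.448). Of 38 mannosylation genes 1, MNN2 (-0.83 ± 0.25), was lower and 0 higher (0 adjusted over the list alone; adjusted p = 0.345). Of 25 genes for wall stress and GPI-anchored proteins, 4 were higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.704), with SSR1 at -1.78 ± 0.29, PGA6 at 2.01 ± 0.56, PGA23 at 1.34 ± 0.37 and PGA13 at 1.302 ± 0.35. ECM331 (1.21) and PGA45 (-1.23), named after their values were seen, were the others. SSR1 was at -1.09 without control replicate 1, and without control replicate 2 PGA23 was at 2.54 and PGA13 at 2.34. Of 28 ergosterol genes, ERG251 (1.10 ± 0.26) and ARE2 (1.05 ± 0.25) were higher and 0 lower (2 and 2 adjusted over the list alone; adjusted p = 0.63). Of the cell wall and membrane genes named here, only CHS1 and SSR1 kept their calls whichever library was left out. CRH11 (1.02), EXG2 (1.33), SCW11 (0.91), CHS4 (-0.59), MNN2 (-0.85), ERG251 (1.06), PGA13 (0.71), PGA23 (0.70) and PGA45 (-0.88) lost theirs without control replicate 1, and SCW11 (0.81), CHT2 (0.94), MNN2 (-0.81) and ARE2 (0.89) without control replicate 2. EXG2 (1.40), SCW11 (0.72), CHS4 (-0.81), CHT2 (0.97), MNN2 (-0.68), ERG251 (0.99), PGA13 (1.22) and PGA23 (1.18) lost theirs without compound 2 replicate 2. EXG2 (1.31), SCW11 (0.95), CHS4 (-0.72), MNN2 (-0.82), ERG251 (1.01), ARE2 (1.00), PGA13 (1.33), PGA23 (1.39), ECM331 (1.3) and PGA45 (-1.3) lost theirs without compound 2 replicate 3. PGA6 (1.05) and ECM331 (0.78) lost theirs without compound 2 replicate 1, where 5 mannosylation genes were lower and 3 ergosterol genes were higher and 1 lower. Without control replicate 2, 1 mannosylation gene was higher and 3 lower, and 1 ergosterol gene was higher and 1 lower. Scaling by library totals gave 3 higher and 6 lower in the glucan list, 2 and 2 in the chitin list, 0 and 2 in mannosylation, 3 and 4 in the wall stress list and 2 and 2 in the ergosterol list.

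In the nutrient uptake lists, HMX1, a heme oxygenase gene, rose 4.02-fold from 72.5 ± 1.75 to 291.5 ± 30.1 CPM, and CRP1, a copper transporter gene, rose 2.39-fold. The iron and copper list had 5 higher and 1 lower of 33 (6 and 3 adjusted over the list alone; camera's adjusted p = 0.224). These counts were 9 and 3 without control replicate 2, 4 and 5 without compound 2 replicate 1, 6 and 0 without compound 2 replicate 2 and 2 and 0 without compound 2 replicate 3, and 3 and 3 when scaled by library totals. Of its heme and iron genes RBT5 and CFL2, the treated and control values overlapped, and without compound 2 replicate 1 their log2 fold changes went from 2.01 and 2.00 to 0.51 and 1.10 with no call. Their calls were also lost without compound 2 replicate 3 (2.39 and 2.12). FRP1 (1.00) and MAC1 (-0.91), named after their values were seen, were the other called members. FRP1 lost its call without control replicate 1 (0.80) or compound 2 replicate 3 (1.06), and MAC1 without control replicate 2 (-0.63) or compound 2 replicate 2 (-0.98) or 3 (-0.81). PUT1 (-1.77 ± 0.26), the urea amidolyase gene DUR1,2 (-1.34 ± 0.29), the proline catabolism gene PUT2 (-1.42 ± 0.31) and the regulator gene ARO80 (-1.39 ± 0.32) were the 4 lower of 28 nitrogen limitation genes. CAR1, an arginase gene named after its values were seen, rose by 1.33 on the log2 scale (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.271). PUT2 and ARO80 were not called without compound 2 replicate 2 (-1.23 and -1.32) or 3 (-1.20 and -1.13). Of 19 hexose transporter genes, 3 were higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.944), with HGT12 at 1.45 ± 0.28, HGT20 at 1.34 ± 0.32, HGT14 at -1.65 ± 0.27 and HGT5 at -1.28 ± 0.28, and HGT1, named after its values were seen, at 0.93. HGT1 was not called without control replicate 1 (1.03) or 2 (0.84), nor was it without compound 2 replicate 2 (0.72) or 3 (0.98). HGT20 (1.17) was not called without compound 2 replicate 2, nor HGT20 (1.33) and HGT5 (-1.12) without replicate 3. Of 26 amino acid and peptide transport genes, 2 were higher and 1 lower (2 and 2 adjusted over the list alone; adjusted p = 0.917). These counts became 4 and 3 without compound 2 replicate 1, and 1 and 4 when scaled by library totals. The lower one, the peptide transporter gene PTR2 (-2.78 ± 0.67), was not called without compound 2 replicate 3 (-2.53), and was at -2.17 without control replicate 2 and -4.13 without compound 2 replicate 2. The higher ones, AGP3 (1.05 ± 0.27) and PTR22 (1.01 ± 0.28), were not called without compound 2 replicate 2 (0.79 and 1.00), and AGP3 also not without control replicate 1 (0.93) or compound 2 replicate 3 (1.13), nor PTR22 without control replicate 2 (0.88).

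The secreted protease gene SAP2 fell 19.4-fold, from 8.45 ± 7.998 to 0.426 ± 0.287 CPM, and PLC2, a phospholipase C gene, rose 2.68-fold. They were the only 2 called of 22 secreted hydrolase genes (1 higher and 1 lower adjusted over the list alone; camera's adjusted p = 0.568). Control replicate 1 gave 14.1 CPM of SAP2 and control replicate 2 gave 2.79 CPM, and without the former the log2 fold change went from -4.28 to -2.68 with no call. It was -5.01 without control replicate 2 and -4.89 without compound 2 replicate 1, and in both of these fits, and when scaled by library totals, 2 hydrolase genes were lower. Of 24 heat shock and chaperone genes, HSP30 (-1.61 ± 0.27) and HSP60 (-0.80 ± 0.23) were lower and 0 higher (0 and 2 adjusted over the list alone; adjusted p = 0.593). HSP60 lost its call without control replicate 1 (-0.68) or compound 2 replicate 2 (-0.79) or 3 (-0.71). In the list for gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, 3 of 27 were higher and 4 lower (3 and 5 adjusted over the list alone; adjusted p = 0.345), with PXP2, an acyl-CoA oxidase gene, at -1.27 ± 0.24. The isocitrate lyase gene ICL1 (1.198 ± 0.28) and the regulator gene CAT8 (1.16 ± 0.24) were higher, and the lactate transporter gene JEN1 (-1.13 ± 0.34) lower. FBP1 (0.97), POX1-3 (-0.92) and ADR1 (-0.83) were named after their values were seen. Of these 7 genes, PXP2 kept its call whichever library was left out. Without control replicate 1, ICL1 (1.07), CAT8 (1.05), FBP1 (0.73), POX1-3 (-0.89) and ADR1 (-0.85) were not called, and without control replicate 2, JEN1 (-0.77) and ADR1 (-0.82). Without compound 2 replicate 1, POX1-3 (-0.79) was not called. Without compound 2 replicate 2, ICL1 (1.01), JEN1 (-0.91), FBP1 (0.85), POX1-3 (-1.03) and ADR1 (-0.87) were not called. The same genes were not called without compound 2 replicate 3 (1.17, -0.90, 0.92, -0.93 and -0.72). Scaling by library totals gave 2 higher and 7 lower in this list. The sodium pump gene ENA21 (1.31 ± 0.26) was the 1 higher of 18 osmotic stress genes, with 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.958). In this list 2 were lower without compound 2 replicate 1, and 1 when scaled by library totals.

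No member was called in 4 further lists, either over all genes or adjusted over the list alone (0 in each). Without control replicate 2, 1 translation factor gene was higher and 1 autophagy gene lower. Without compound 2 replicate 1, 1 translation factor gene and 1 autophagy gene were lower and 1 mitochondrial ribosomal protein gene higher, and scaling by library totals gave 1 and 2 lower in the first and the autophagy list. Camera's adjusted p-values were 0.0576 for 27 translation factor genes, 0.464 for 16 mitochondrial ribosomal protein genes, 0.761 for 15 autophagy and vacuolar protease genes and 0.878 for 11 genes of the TLO family, whose near-identical copies share reads. TIF11 (0.64 ± 0.24) and GCD2 (-0.62 ± 0.24) had the smallest p-values among the translation factors, MRP2 (0.59 ± 0.26) among the mitochondrial ribosomal proteins and VPS34 (-0.78 ± 0.28) among the autophagy genes. Median, mean and test differed in sign for the opaque and mating, glucan, amino acid transport, hexose transporter, yeast-form and osmotic stress lists.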

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

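The run without ribosomal RNA genes was chosen after the data were seen, and all other alternatives before. No direction of a called result reversed (0 of the named genes and lists). The main counts were 297 genes higher and 207 lower, 218 and 139 of them by at least 2-fold, and 13 lists higher and 1 lower. With library totals as the only scaling they were 184 and 414, and 133 and 267 by at least 2-fold. These totals omit the composition factors that TMM adds. With the replicate number as a block (replicate block) 134 genes were lower, and 350 of the 504 calls were kept, but the sample titles do not say that equal numbers pair samples. Compound 2 replicate 3 has no control of the same number, so that fit drew nothing on the difference from it. Lost calls there can reflect the loss of that library as well as the block. Deviations of same-numbered libraries correlated at -0.04 and 0.18 over the 2 pairs. This cannot decide whether they are paired, because with 2 controls each correlation recurs with the opposite sign. Leaving out 1 library gave between 141 and 452 genes higher, 78 and 425 lower, 140 and 317 higher by at least 2-fold, and 78 and 262 lower by at least 2-fold. A group left with 1 library was assumed to vary like the other. Leaving out 1 library gave between 12 and 15 lists higher and 1 and 2 lower. With a correlation estimated per list, 0 lists were higher and 0 lower, and with fry 5 were higher and 0 lower. The planted list in the simulation was missed by the former test too, but simulated genes varied independently, so this does not set the losses aside. The estimated correlations of the 14 called lists lay between -0.039 (endoplasmic reticulum) and 0.555 (proteasome), against the preset 0.01. The cause of the other differences was not tested. Of 108 named genes called, 59 kept their call in all 15 alternatives (14 for RDN58), and the most calls (36) were lost without compound 2 replicate 2 and without compound 2 replicate 3. Of the 14 called lists, 0 were kept in all 12 alternatives. The estimated correlation lost all 14, and fry lost 9 of them. DESeq2 called 441 higher and 279 lower. Depth limits genes with few counts, such as PTR2 at 0.995 CPM in the treated libraries.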

Other observations

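The 3 tests on the branched-chain amino acid genes and the sphingolipid and inositol lists were chosen after the results were seen. The 5 tests on RDN58 and on MDR1 and the genes beside it were set down before the values of the tests were seen, but after the changes they address. Some genes named here were not taken by the rule for named genes, and those of the next 2 paragraphs were chosen after their values were seen.

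A few genes of inositol and sphingolipid metabolism fell beside INO1. ITR1, an inositol transporter gene, was 2.89-fold lower (log2 -1.53 ± 0.24, n = 2 controls and 3 treated libraries), and MIT1, which encodes a mannosyltransferase of inositolphosphorylceramides, was 3.25-fold lower (log2 -1.70 ± 0.27). Of 17 sphingolipid synthesis genes, 5 were lower and 0 higher: SUR2, AUR1, MIT1, FEN1 (-1.50 ± 0.33) and LCB2 (-0.87 ± 0.23). When scaled by library totals 8 were lower, 7 were without compound 2 replicate 1, and 4 without compound 2 replicate 2 or 3. SUR2 went from -1.95 to -1.09 without control replicate 1 and kept its call. FEN1 lost its call without control replicate 1 (-1.0), and LCB2 without control replicate 1 (-0.67) or compound 2 replicate 2 (-0.86) or 3 (-0.78). Limma's camera gave adjusted p = 0.0124, and adjusted p = 0.236 with an estimated correlation. Without the genes that led to the list, 2 of 14 were lower (camera's adjusted p = 0.196), so the remaining members were not shown to differ from other genes. Fry, which does not compare members with other genes, gave adjusted p = 0.0184 for the full list. It gave adjusted p = 0.0397 for the remaining members, both in the lower direction. Of 11 inositol and phospholipid synthesis genes, 2 were lower, INO1 and ITR1 (camera's adjusted p = 0.0248, and adjusted p = 0.236 with an estimated correlation). Without these 0 of 9 were called (camera's adjusted p = 0.288). Fry gave adjusted p = 0.0144 for the full list and adjusted p = 0.0184 without these genes, both in the lower direction.

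Several of the strongest changes were in genes without a symbol, which made up 193 of the 504 calls. C4_01800W_A rose 13.5-fold, from 1.58 ± 0.444 to 21.2 ± 4.77 CPM, and C1_04010C_A rose 5.67-fold, from 14.96 ± 0.809 to 84.8 ± 6.67 CPM. C5_04480C_A fell from 25.8 ± 8.39 to 2.93 ± 0.736 CPM, and C5_01300C_A from 19.6 ± 9.70 to 2.52 ± 0.770 CPM (log2 -2.95, and -2.33 without control replicate 1). The mitochondrial genome held between 0.00496% and 0.00507% of counts in the controls and between 0.00783% and 0.014% in the treated libraries.

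The rise of leucine, isoleucine and valine synthesis genes was weighed against 3 explanations. For scaling between libraries, the lowest list median over 4 scalings was 1.127 (highest 1.345), so the choice between these scalings does not account for the rise. The test could hardly have ended otherwise, because the largest move of the median of all genes between them was -0.20, with library totals alone. A rise of every amino acid branch is argued against, because the 7 arginine synthesis genes had a median of -0.814 (95% bootstrap bounds over genes -1.234 to -0.442). A general rise of amino acid synthesis genes cannot be told apart from a rise of this branch, since the list median exceeded that of the other amino acid genes by 0.911 with bounds of -0.106 to 1.317. A response to blocked leucyl-tRNA charging is a candidate explanation that these data do not test, and the regulator genes GCN4 (0.48 ± 0.24, adjusted p 0.222 in edgeR) and LEU3 (-0.50 ± 0.25, adjusted p 0.227) were not called.

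MDR1, IFD6, OYE32, GRP2 (3.60-fold, log2 1.85 ± 0.25) and CSH1 (3.40-fold, log2 1.77 ± 0.25), a set often seen together in strains with raised MDR1, were all higher. The set was defined by its rise in these data, so that its members rose together is not a separate result. Reads shared between paralogs are argued against, because 0 of the 5 genes had a non-whole count in any library. A response through the oxidative stress regulator Cap1 may contribute, but the values leave it open. Over 11 target genes of Cap1, the median log2 fold change was 0.632 with bounds over genes of 0.073 to 1.051, and 4 were higher and 0 lower. Camera gave adjusted p = 0.00499, or adjusted p = 0.258 with an estimated correlation, and fry gave adjusted p = 0.0414. Without compound 2 replicate 2 or 3, or when scaled by library totals, 2 were higher, and 5 were without compound 2 replicate 1. For the regulator Tac1, 6 target genes had a median of 0.25 (bounds -0.205 to 0.84; 1 higher and 0 lower, camera's adjusted p = 0.288), and CDR1 (0.03 ± 0.27) and CDR2 (0.25 ± 0.25), both of which this explanation required to rise, were not called, though the bounds do not exclude it. The regulator genes MRR1 (0.68 ± 0.25, adjusted p 0.105 in edgeR) and CAP1 (0.25 ± 0.23, adjusted p 0.546) were not called, and activity of these regulators was not measured.

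RDN58 fell while RDN18 and RDN25, the genes of the large ribosomal RNAs, had log2 fold changes of 0.24 ± 0.27 and 0.42 ± 0.30, and the short ribosomal RNA gene RDN5 had 1.19 ± 0.58 (adjusted p 0.218 in edgeR, from 3.53 ± 3.03 to 8.02 ± 5.10 CPM). A difference in the removal of all ribosomal RNA is argued against, because the higher of their lower limits was -0.18 (each fold change minus 2 SE). Loss of short RNAs during preparation could still account for it, since 5 small RNA genes had a median of 0.067 with bounds of -2.351 to 0.782, too wide to decide. Of these 5, the 1 small nuclear RNA gene was at -2.351, and the 4 small nucleolar RNA genes had a median of 0.243. RDN5 runs against a loss of short RNAs and the small nuclear RNA gene goes with it. Each is a single gene, and RDN5 was at few counts. A biological cause was not tested.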
